A study of Solanum tuberosum subsp. andigenum with 10 samples.

How the data were processed

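RNA from stolons of Solanum tuberosum ssp. andigena was measured on 10 2-colour Agilent 4x44K potato arrays, each with 1 condition in Cy5 and another in Cy3. The 5 conditions were LD, SD2, SD4, SD6 and SD8, each on 4 arrays. Per the labels' protocols, stolons were collected in the dark before the lights came on, and total RNA was amplified and coupled to the dyes through amino-allyl nucleotides. Spot and background brightness are given per the file headers as intensity, without normalization, from Agilent Feature Extraction 9.5.1.1. Per the file headers, the log ratio column is the log10 of red over green processed signals, and the processed signals are again an intensity, after subtraction of a background surface, multiplicative detrending, and linear and lowess dye normalization on rank-consistent probes. The other columns used, per the file headers, are flags (0 or 1).

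The deposited table holds log2 ratios of Cy5 over Cy3 for 9 arrays, with a slope of 3.32 on the scanner's log10 ratios. The deposited column of the LD and SD2 array is in log10 units, with a slope of 1.00 and a standard deviation of 0.35. The medians of the deposited columns lay between -0.15 and 0.07 in their own units, so the scanner's centring was kept, and between 22.3% and 27.1% of the values per column were null. The table was used only as an alternative, with the log10 column rescaled.

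Brightness per spot was read from the scanner files, and 1417 control spots were left out, which gave 42034 probes. A probe was kept when it was well above background in at least 4 of the 20 channels (38314 probes, of which 38313 could be tested). The share of probes well above background ran from 72.6% to 93.8% in the green channel and from 59.9% to 95.5% in the red one. Spots marked as outliers by the scanner software were set to missing (814 spots, of which 689 lay on the SD2 and SD4 array). Background was corrected by normexp with an offset of 50, and log ratios were normalized within each array by loess, with limma 3.58.1 in R 4.3.3 and its data.table package (version 1.17.8). A linear model with an intercept for the dye and 4 coefficients for the conditions relative to LD was fitted to each probe, with 5 residual degrees of freedom for a probe present on all 10 arrays. The median residual standard deviation was 0.23, the median size of the dye effect was 0.32, and empirical Bayes moderation used 2.50 prior degrees of freedom. The number of arrays limits the precision.

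The contrasts were fixed beside an F test over the 5 conditions and a linear trend over the short days SD2 to SD8: each short-day stage against LD, and each stage against the one before. Probes with a Benjamini-Hochberg adjusted p below 0.05 were called. No paired analysis was possible because the labels number no replicates across the arrays. Slides 1 to 3 were scanned in a first session (6 arrays) and slide 4 in a second (4 arrays), as read from the scanner files. In the first session SD4 lay on the LD and SD4 array alone. In the second, LD lay on the SD8 and LD array alone. The spread between arrays includes no known biological replicate.

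Annotation came from the text in the scanner files. On the array 14425 probes had no hit in that text, and 0 of its accessions matched the RefSeq list of potato genes, so that no genome position is given. A total of 23 gene lists were defined by text patterns on product names: storage proteins, protease inhibitors, starch synthesis, starch breakdown, sucrose metabolism and transport, gibberellin, flowering and tuberization regulators, circadian clock, cell cycle, cell wall, photosynthesis, auxin, cytokinin, abscisic acid, jasmonate, ethylene, pathogenesis-related proteins, heat shock proteins, suberin, phenylpropanoids, glycoalkaloids and sterols, root uptake markers and ribosomal proteins. The lists and their patterns were fixed before the data were examined. Text patterns admit false members, such as DIR1 in the protease inhibitors, an orcinol O-methyltransferase in the clock and regulator lists through the species name Rosa gigantea, a plastocyanin-like probe in photosynthesis and adenosylhomocysteinase in cytokinin. Lists were tested against all other probes with camera at a preset correlation of 0.01 and again with an estimated correlation, and fry was run beside them. List tests of adjacent stages, and 3 marker lists (long transcripts, short transcripts and leaf enzymes), were added after first results had been seen.

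Named probes followed a rule fixed before the data were examined. It took called probes with a named product and the same sign on the array that holds both conditions: the 12 largest rises and falls for SD8 vs LD, 6 each for the other comparisons with LD, and 4 each for adjacent stages and the trend. It took 1 probe per annotation text, up to 4 members of each list with the smallest p in SD8 vs LD, and each regulator or gibberellin probe called in any comparison with LD. In all 232 probes came under the rule. The text pattern that decides which annotation names a product was refined after the annotation and first results had been seen, which affects the probes the rule could take. Where a named probe was well above background in 0 of the 4 channels of 1 condition, its fold change is given as a bound. Probes with few such channels have fitted values that the background limits.

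The fit was tested on simulated data: differences between SD8 and LD were planted in some of 38313 probes, at 67 probes by 1.5-fold, 67 by 2-fold and 66 by 4-fold. Of these 23.9%, 53.7% and 86.4% were called, and 4 calls (3.54%) were false. Few probes were changed and errors were independent between arrays in the simulation, so these shares need not hold for the real data. The model had been run once before that test was written. The alternatives fixed beforehand were no background subtraction, the scanner's own log ratio, median centring, scaling between arrays, no filter or a filter on all 20 channels, no dye term, the slide as a fixed or random block (a correlation of 0.545 within slides), outlier spots kept, a trended and robust prior, array weights, separate channels (an intraspot correlation of 0.666), the deposited values, and leaving out each array. Added after the data had been seen were the deposited table read as log2 throughout, a minimum of 2-fold, the first scan session alone, the scan session as a block, and fits without the 4 SD4 or the 4 LD arrays.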

Results

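Gene expression was measured in the stolons of Solanum tuberosum ssp. andigena, a potato whose stolons (underground shoots) swell into tubers when days are short. Stolons came from plants in long days (LD) and from plants after 2, 4, 6 or 8 short days (SD2, SD4, SD6 and SD8). Each of 10 Agilent 2-colour arrays compared 2 of these 5 conditions. Every pair of conditions met on 1 array, and each condition lay on 4 arrays, 2 times in Cy5 and 2 times in Cy3. The labels do not say whether the 4 channels of a condition held separate plants or the same extract, so all p-values measure the spread between arrays, which may be technical only. The protocol text gives identical hours of light for both day lengths, and the day lengths used here are those of the sample titles. Median spot brightness before background correction ran from 848 to 2204 in the green channel and from 166 to 2441 in the red one, and the number of arrays limits the precision. LD was the dimmest condition in both colours. Its medians were 166 and 258 in red (LD and SD2, LD and SD4 arrays) and 848 and 1203 in green (SD6 and LD, SD8 and LD arrays). Each comparison with LD rests on these channels. Of 42034 probes, 38313 were tested. Values are log2 fold changes with their standard error, fitted over all 10 arrays unless stated otherwise, and a probe is named by its product in the files and its identifier.

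A linear contrast over SD2 to SD8 asks which genes ended higher or lower with the number of short days, and its slope is an average that does not show a steady change. Gibberellin 2-oxidase 1 (MICRO.8269.C1), which inactivates the growth hormone gibberellin, had a slope of 1.17 ± 0.05 log2 units per short day (adjusted p = 3.6e-06), with -0.01 from SD2 to SD4, 4.58 from SD4 to SD6 and 1.66 from SD6 to SD8. A germin-like protein (MICRO.8382.C12) had a slope of 1.17 ± 0.04, with steps of -0.42, 3.94 and 3.00. The slope was 1.23 ± 0.07 for an alcohol dehydrogenase (MICRO.3874.C1, fitted on 9 arrays) and 1.11 ± 0.06 for a pathogenesis-related protein (MICRO.5426.C4). The xyloglucan endotransglycosylase LeXET2 (MICRO.4152.C2), an enzyme that loosens cell walls, had a slope of -0.82 ± 0.03, with steps of -1.23, -3.29 and 0.16, and its relative XTH7 (MICRO.4590.C1) one of -0.76 ± 0.03. For a gamma-thionin-like defence peptide (MICRO.839.C12) the slope was -0.71 ± 0.02, with steps of 0.39, -3.13 and -0.92. A linear trend over short days passed limma's test at 19563 probes, of which 10208 had a positive and 9355 a negative slope, and 24063 probes differed among the 5 conditions by its F test. With the slide as a block these counts were 19318 and 24569, and in the 6 arrays of the first scan session alone they were 13101 and 19192. Without a dye term they were 6451 and 7435.

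**Figure D1:**
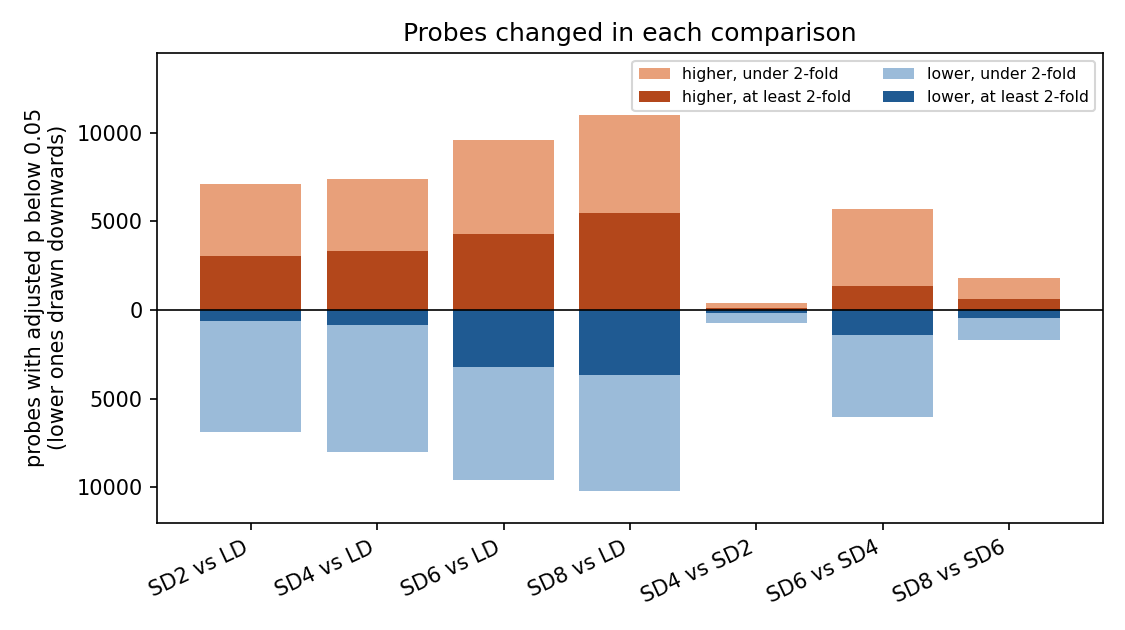
Number of probes (vertical axis) with an adjusted p below 0.05 in each comparison (horizontal axis), with higher probes drawn upwards and lower ones downwards, and darker bars for changes of at least 2-fold. The bars reach 11003 higher and 10215 lower probes in SD8 vs LD and are shortest for SD4 vs SD2, with 365 higher and 749 lower.

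The comparison of SD8 with LD asks how stolons after the longest induction differ from those of non-induced plants. Patatin, the main storage protein of tubers, had the largest rise among probes with a named product (MICRO.1520.C3, 7.46 ± 0.65, adjusted p = 6e-05). Sucrose synthase (MICRO.196.C8), which opens the path from sucrose to starch, rose by 6.34 ± 0.21, and gibberellin 2-oxidase 1 (MICRO.8269.C1) rose by 6.07 ± 0.29. The alcohol dehydrogenase (6.37 ± 0.40, 9 arrays) and the germin-like protein (6.28 ± 0.27) rose as far. The gamma-thionin-like peptide fell by 6.11 ± 0.15, and beta-fructofuranosidase (MICRO.4223.C2), an invertase that splits sucrose without conserving its bond energy, fell by 5.73 ± 0.26. Further large falls were those of the peripheral-type benzodiazepine receptor (-4.63 ± 0.28), proteinase inhibitor II (-4.40 ± 0.43), XTH7 (-4.26 ± 0.17) and a Nod26-like membrane channel (-4.26 ± 0.14).

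Starch genes were higher in SD8 stolons. Of 77 starch synthesis probes, 54 rose and 1 fell (55 and 1 adjusted over the list alone), with a median of 1.43 (camera adjusted p = 6.85e-10; adjusted p = 0.402 with an estimated correlation). Branching enzyme, which puts branch points into starch, rose at both leading probes (MICRO.1689.C3, 5.17 ± 0.19; MICRO.1689.C4, 5.05 ± 0.18). Plastidic phosphoglucomutase (MICRO.1743.C1) rose by 5.54 ± 0.26, the plastidic ATP/ADP transporter by 5.52 ± 0.31 and starch synthase (MICRO.920.C3) by 5.41 ± 0.24. Starch breakdown probes rose at 22 of 41 and fell at 7 (23 and 7 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 0.0159; adjusted p = 0.431 with an estimated correlation), among them alpha-amylase (MICRO.4817.C1, 2.09 ± 0.09). Storage protein probes rose at 42 of 64 and fell at 8 (42 and 8 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 7.88e-06; adjusted p = 0.314 with an estimated correlation). Protease inhibitors, which are stored in tubers and defend them, rose at 91 of 170 probes and fell at 21 (93 and 23 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 7.88e-06; adjusted p = 0.314 with an estimated correlation). A Kunitz-type inhibitor (bf_mxflxxxx_0007b07.t3m.scf) rose by 2.55 ± 0.10, whereas wound-inducible proteinase inhibitor I (MICRO.5302.C1) fell by 4.14 ± 0.15. The text pattern also drew in DIR1 proteins, lipid transfer proteins with no inhibitor function, at 3.43 ± 0.13 and -3.36 ± 0.13.

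Genes of cell division and of ribosomes were higher in SD8. Cell cycle and DNA replication probes rose at 62 of 110 and fell at 13 (63 and 15 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 2.57e-05; adjusted p = 0.431 with an estimated correlation). Cyclin A1 (cSTA29A10TH, 2.94 ± 0.14), the replication licensing factor MCM3 (2.78 ± 0.14) and an aurora-like kinase (MICRO.2261.C2, 1.92 ± 0.10) were among them. Ribosomal protein probes rose at 183 of 346 and fell at 11 (183 and 11 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 7.45e-08; adjusted p = 0.402 with an estimated correlation). Heat shock and chaperone probes rose at 114 of 267 and fell at 58 (115 and 58 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0286; adjusted p = 0.489 with an estimated correlation), led by a heat shock 70 protein (MICRO.5939.C1, 4.63 ± 0.17). Pathogenesis-related and defence probes rose at 65 of 121 and fell at 26 (67 and 28 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.0133; adjusted p = 0.431 with an estimated correlation), for example osmotin-like protein (MICRO.1588.C2, 2.93 ± 0.12). Photosynthesis probes fell at 71 of 138 and rose at 13 (72 and 13 adjusted over the list alone), with a median of -0.71 (camera adjusted p = 7.88e-06; adjusted p = 0.426 with an estimated correlation), for example the chlorophyll-binding protein CP29 (MICRO.846.C1, -3.09 ± 0.10).

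The gibberellin list went both ways in SD8. Of its 43 probes, 23 fell and 11 rose (23 and 11 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.0261; adjusted p = 0.402 with an estimated correlation). That call was lost without the SD8 and LD array, where the median was -0.41. Gibberellin 3-beta-hydroxylase 1, which makes active gibberellin, fell by 2.58 ± 0.19, the gibberellin-responsive gast1 (MICRO.11045.C1) fell by 2.15 ± 0.10 and the related snakin-1 (MICRO.12055.C1) stood at -2.84 ± 0.13. Other probes annotated as gibberellin 2-oxidase 1 went against MICRO.8269.C1. MICRO.7232.C1, well above background in 2 of 4 SD8 channels, fell by 1.99 ± 0.19 and cSTB42I1TH, not well above background in SD8, was at least 3.15-fold lower. Among flowering and tuberization regulators, 31 of 71 probes rose and 21 fell (32 and 21 adjusted over the list alone), with a median of 0.31 and no call by camera (adjusted p = 0.382). BEL1-related homeotic protein 5, a transcription factor that promotes tubers, rose at each of its 7 named probes, but by between 1.03 ± 0.30 (cSTE9H8TH) and 4.01 ± 0.25 (bf_mxlfxxxx_0001c05.t3m.scf). Regulator probes were named only where called in a comparison with LD. The lowest of these 7 lost its call without the SD8 and LD array, at 0.67. It stood at 0.71 in the first scan session and at -0.04 in the second, without dye correction. An APETALA2 homolog (MICRO.2753.C1, -2.53 ± 0.09), a CONSTANS-like protein (MICRO.13353.C3, -1.52 ± 0.11) and self-pruning interacting protein 1 (MICRO.8759.C1, -1.44 ± 0.12) fell. A probe for a flowering locus T like protein stood at -0.19 ± 0.19 in SD8 vs LD (adjusted p = 0.45). It came under the naming rule through a call in another comparison, so this value does not mean that it stayed unchanged throughout.

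In all, 21218 of 38313 probes passed limma's test in SD8 vs LD, 11003 higher and 10215 lower, and 9139 of them differed by at least 2-fold (5476 higher, 3663 lower). The counts were 21916 with the slide as a block and 14211 in the 6 arrays of the first scan session, 10515 without the 4 SD4 arrays and 9006 without a dye term. The 4 arrays of the second session can be fitted only without a dye term and leave no degrees of freedom for a test of their own. Their fold changes from LD therefore carry the dye effect (median size 0.32). In SD2 and SD4 vs LD it adds up over several arrays. Across probes, which are not independent replicates, the fold changes of the sessions correlated at 0.684 in SD8 vs LD. The second session's values here are those of the SD8 and LD array alone, which had the largest residual standard deviation (0.41). Its other comparisons with LD also run through that array. The median of the protease inhibitors was 0.83 in the first session and 0.30 in the second, and that of photosynthesis was -0.35 and -0.84. Products of long transcripts lay 0.33 above those of short ones.

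**Figure D2:**
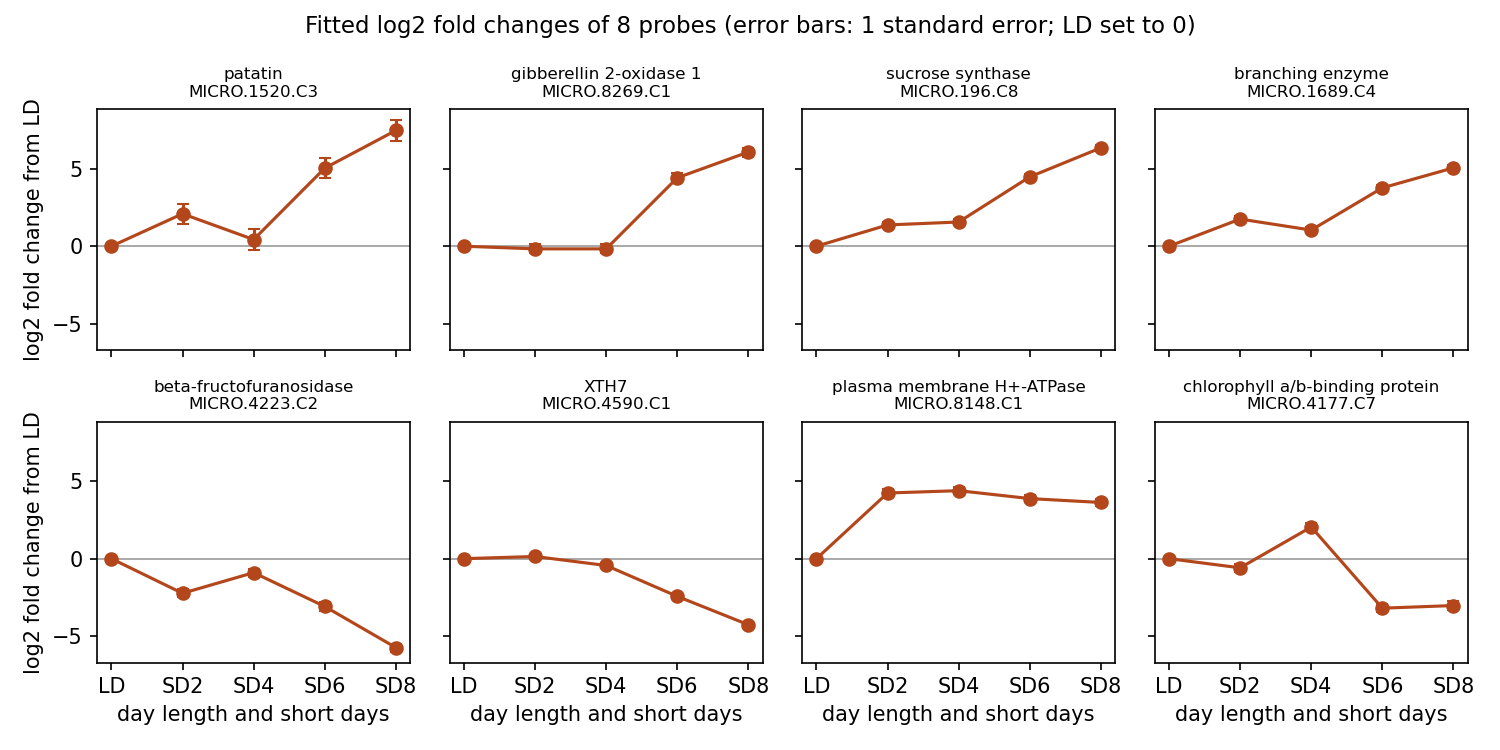
Fitted log2 fold change from LD (vertical axis, LD set to 0, error bars 1 standard error over 10 arrays) of 8 probes at each stage (horizontal axis). Patatin, gibberellin 2-oxidase 1, sucrose synthase and branching enzyme reach 7.46, 6.07, 6.34 and 5.05 in SD8, while the plasma membrane H+-ATPase is already at 4.23 in SD2 and the chlorophyll a/b-binding protein peaks at 2.04 in SD4.

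SD2 was compared with LD to find the earliest changes. The largest rises were those of a plasma membrane H+-ATPase (MICRO.8148.C1, 4.23 ± 0.23, adjusted p = 6.4e-05), which acidifies the cell wall, and of a putative auxin transport protein (MICRO.11119.C1, 4.04 ± 0.24). A protein of the AAA family (3.74 ± 0.41), an F-box protein (MICRO.6414.C1, 3.72 ± 0.30) and a coatomer subunit (3.61 ± 0.25) followed. The H+-ATPase, auxin transport, AAA and F-box probes still stood at 3.62, 2.94, 4.06 and 3.82 in SD8 vs LD. Standard deviations over their LD channels were 0.82, 0.72, 1.16 and 0.95 log2 units, against 0.24, 0.35, 0.12 and 0.14 in SD2. For these probes an early response cannot be told apart from a difference of the LD sample. The largest falls included pSTH-21 at -3.83 ± 0.14, PAR-1c at -3.79 ± 0.18, pSTH-2 at -3.74 ± 0.21 and TSI-1 at -3.51 ± 0.22, while the pathogenesis-related and defence list was not called (median -0.17, camera adjusted p = 0.0971). Protease inhibitors fell at 66 of 170 probes and rose at 1 (67 and 1 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 4.04e-06; adjusted p = 0.49 with an estimated correlation). Photosynthesis probes fell at 35 of 138 and rose at 2 (34 and 2 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 8.1e-05; adjusted p = 0.634 with an estimated correlation). Starch synthesis probes rose at 27 of 77 and fell at 2 (27 and 2 adjusted over the list alone, median 0.38, camera adjusted p = 0.00102, and 0.634 with an estimated correlation). Flowering and tuberization regulators rose at 24 of 71 and fell at 5 (26 and 5 adjusted over the list alone, median 0.18, camera adjusted p = 0.00512, and 0.634 with an estimated correlation). A BEL1-related homeotic protein 11 probe (MICRO.819.C2) was among the regulators that rose, at 2.01. By limma's test 13989 probes differed, 7095 higher and 6894 lower. Of the 3690 with at least a 2-fold change 3054 were higher and 636 lower. A set of products of long transcripts lay 0.24 above one of short transcripts in SD2 vs LD. Without the 4 SD4 arrays 1099 probes passed (81.8% of them higher, against 50.7% over all arrays), without a dye term 1956 (77.8% higher), without the LD and SD2 array 5554 (65.6% higher), in the first scan session 8592 and with the slide as a block 13607. Across probes the fold changes of the scan sessions correlated at 0.354. The values of the second session add up the dye effects of several arrays here, so this is no clean measure of how far the sessions match. In the first session, the second session and with median centring, the list medians were -0.17, -0.08 and -0.999 for photosynthesis, 0.16, 0.86 and 0.42 for starch synthesis, -0.33, -0.94 and -0.77 for protease inhibitors, and 0.28, 0.30 and 0.44 for the regulators.

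After 4 short days the same transporters headed the rises against LD, with the auxin transport protein at 4.42 ± 0.24 (adjusted p = 4.6e-05) and the H+-ATPase at 4.38 ± 0.23. Phosphoenolpyruvate carboxylase (MICRO.13891.C1, 3.96 ± 0.19) and a beta-galactosidase (cSTA29E8TH, 4.10 ± 0.53) joined them. Among the falls were 2 inhibitors of proteases, a Kunitz trypsin inhibitor (SSBN001F17u.scf, -3.55 ± 0.13) and cysteine protease inhibitor 1 (MICRO.4288.C13, -3.43 ± 0.11), beside PAR-1c (-3.93 ± 0.18) and pSTH-21 (-3.77 ± 0.14). Protease inhibitors fell at 103 of 170 probes and rose at 0 (108 and 3 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 1.09e-15; adjusted p = 0.073 with an estimated correlation). Pathogenesis-related and defence probes fell at 48 of 121 and rose at 14 (49 and 14 adjusted over the list alone, median -0.32, camera adjusted p = 0.00198, and 0.62 with an estimated correlation). Photosynthesis probes rose at 63 of 138 and fell at 7 (65 and 7 adjusted over the list alone, median 0.39, camera adjusted p = 5.09e-07, and 0.62 with an estimated correlation). Starch synthesis rose at 26 of 77 probes and fell at 5 (26 and 5 adjusted over the list alone, median 0.22, camera adjusted p = 0.00405, and 0.62 with an estimated correlation). Flowering and tuberization regulators rose at 25 of 71 and fell at 9 (26 and 9 adjusted over the list alone, median 0.29, camera adjusted p = 0.0068, and 0.62 with an estimated correlation). In total 15417 probes passed limma's test, 7379 higher and 8038 lower, with 3336 higher and 842 lower by at least 2-fold. The long-transcript products lay 0.27 above the short ones. Without a dye term 2610 passed (71.5% higher, against 47.9% with it), without the LD and SD4 array 7332, in the first scan session 3556 (of which 75.3% were higher) and with the slide as a block 15242. In that session SD4 lay on the LD and SD4 array alone. Across probes the scan sessions correlated at 0.62, with dye effects likewise added up in the second session. In the same 3 settings the list medians were 0.29, 0.76 and 0.31 for photosynthesis, 0.26, 0.90 and 0.37 for starch synthesis, -0.91, -1.16 and -1.25 for protease inhibitors, 0.27, 0.13 and 0.46 for the regulators, and -0.34, -0.44 and -0.38 for defence.

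By 6 short days starch and storage genes led the rises against LD. The glucose-6-phosphate/phosphate translocator 2 (174G02AF.esd), which imports the carbon for starch into plastids, rose by 5.08 ± 0.37 (adjusted p = 3.2e-05), patatin (MICRO.1520.C3) by 5.03 ± 0.65, plastidic phosphoglucomutase by 4.85 ± 0.26, the plastidic ATP/ADP transporter by 4.54 ± 0.31 and sucrose synthase by 4.47 ± 0.21. The peripheral-type benzodiazepine receptor (-5.47 ± 0.28), the gamma-thionin-like peptide (-5.18 ± 0.15), an unconventional myosin (-4.76 ± 0.14), proteinase inhibitor II (-4.63 ± 0.43) and the homeodomain factor ATHB-7 (-4.57 ± 0.17) fell furthest. Starch synthesis rose at 53 of 77 probes and fell at 3 (54 and 3 adjusted over the list alone, median 0.93, camera adjusted p = 2.84e-09, and 0.558 with an estimated correlation). Storage proteins rose at 31 of 64 and fell at 6 (31 and 6 adjusted over the list alone, median 0.41, camera adjusted p = 0.00307, and 0.558 with an estimated correlation). Ribosomal proteins rose at 190 of 346 and fell at 6 (194 and 6 adjusted over the list alone, median 0.50, camera adjusted p = 2.49e-10, and 0.558 with an estimated correlation). Cell cycle probes rose at 60 of 110 and fell at 13 (62 and 16 adjusted over the list alone, median 0.56, camera adjusted p = 1.98e-05, and 0.558 with an estimated correlation). Photosynthesis fell at 60 of 138 and rose at 7 (60 and 7 adjusted over the list alone, median -0.52, camera adjusted p = 4.51e-06, and 0.558 with an estimated correlation). Protease inhibitors fell at 53 of 170 and rose at 27 (53 and 27 adjusted over the list alone, median -0.17, camera adjusted p = 0.0404, and 0.558 with an estimated correlation). Defence probes rose at 49 of 121 and fell at 26 (51 and 26 adjusted over the list alone, median 0.27, camera adjusted p = 0.0478, and 0.619 with an estimated correlation). Heat shock and chaperone probes rose at 102 of 267 and fell at 53 (104 and 56 adjusted over the list alone, median 0.17, camera adjusted p = 0.0404, and 0.627 with an estimated correlation). By limma's test 19202 probes differed, 9612 higher and 9590 lower, and 7471 of them by at least 2-fold. The count was 20652 with the slide as a block and 14808 in the first scan session, 7312 without the 4 SD4 arrays and 6731 without a dye term. The fold changes of the sessions correlated at 0.760 across probes. In the first session, the second and with median centring, the medians were -0.30, -0.96 and -0.89 for photosynthesis, 0.81, 1.48 and 1.05 for starch synthesis and -0.17, -0.44 and -0.56 for protease inhibitors. Long-transcript products lay 0.28 above short ones.

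**Figure D3:**
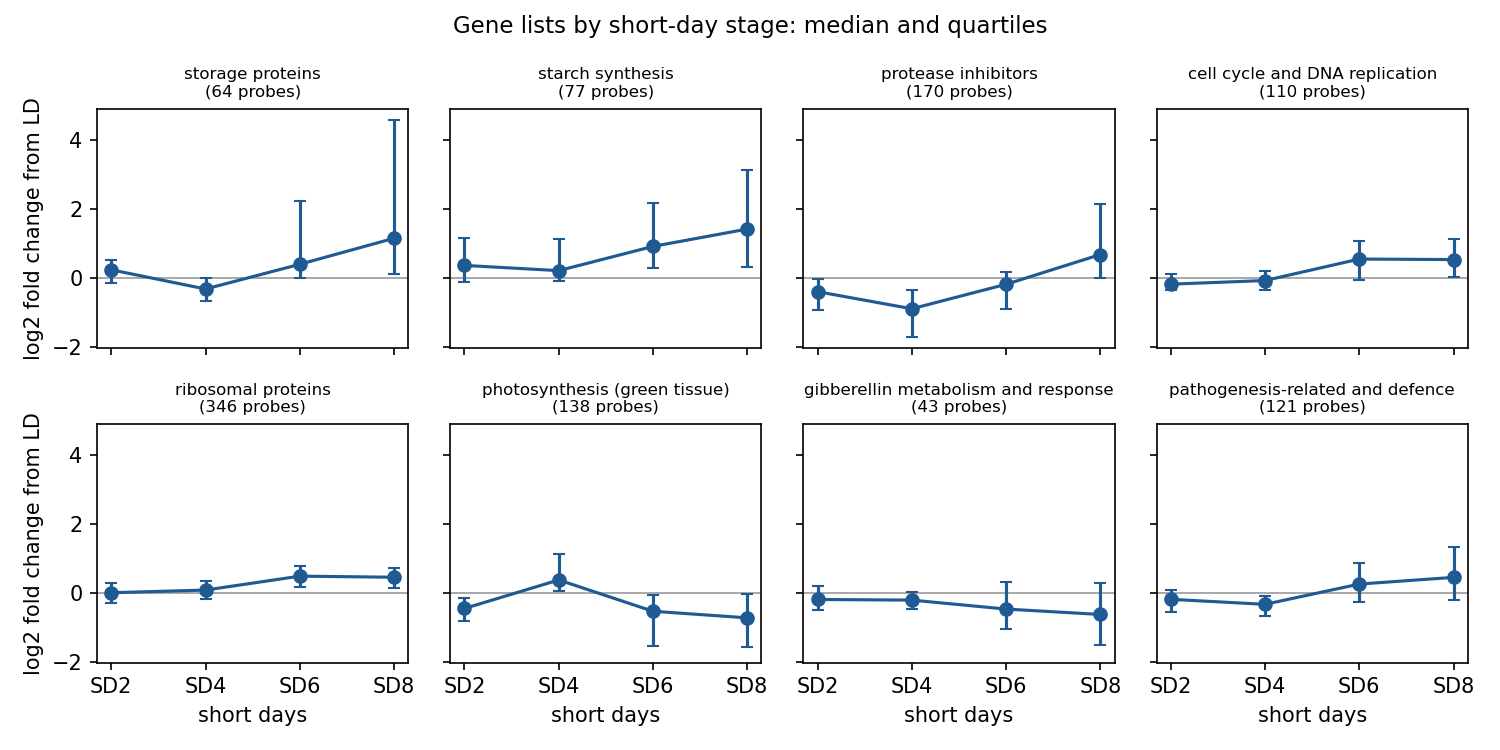
Median log2 fold change from LD (vertical axis, error bars from the lower to the upper quartile of probes) of 8 gene lists at each short-day stage (horizontal axis). Starch synthesis goes from 0.38 in SD2 to 1.43 in SD8, protease inhibitors from -0.88 in SD4 to 0.69 in SD8, and photosynthesis peaks at 0.39 in SD4.

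Adjacent stages were compared to see when genes changed. From SD2 to SD4, probes for the light-harvesting machinery had the largest rises, with a chlorophyll a,b binding protein (MICRO.4180.C3, well above background in 2 of 4 SD2 channels) at 3.47 ± 0.49 (adjusted p = 0.015) and the photosystem I subunit PSI-H (MICRO.9133.C2) at 3.28 ± 0.46 (adjusted p = 0.014). A putative miraculin (MICRO.7365.C1, -2.82 ± 0.13), multicystatin (cSTS30B11TH, -2.53 ± 0.23) and patatin (MICRO.1520.C14, -2.53 ± 0.44) fell. Photosynthesis rose at 59 of 138 probes and fell at 0 (82 and 1 adjusted over the list alone, median 0.98, camera adjusted p = 2.05e-40, and 0.0577 with an estimated correlation). Protease inhibitors fell at 38 of 170 and rose at 1 (71 and 7 adjusted over the list alone, median -0.43, camera adjusted p = 3.18e-16, and 0.0577 with an estimated correlation). Storage proteins fell at 5 of 64 and rose at 1 (15 and 1 adjusted over the list alone, median -0.52, camera adjusted p = 9.71e-08, and 0.246 with an estimated correlation). By limma's test 1114 probes differed, 365 higher and 749 lower. With the slide as a block limma called 0 (7432 had an unadjusted p under 0.05) and in the first scan session 4 (1853 unadjusted). Each of the probes named here lost its call under both. Leaving out the SD2 and SD4 array left 17 probes, and each named probe except the miraculin then lost its call. Without 1 other array the counts were 131 (SD4 and SD6), 209 (SD4 and SD8), 282 (LD and SD4), 336 (LD and SD2), 433 (SD2 and SD6), 588 (SD8 and SD2), 598 (SD6 and SD8) and 3068 (SD8 and LD), so that the count for this step is not firm. In the first and second session the median was 0.46 and 1.03 for photosynthesis, -0.42 and -0.20 for storage proteins and -0.38 and -0.30 for protease inhibitors. For this step the second session's values rest on the SD2 and SD4 array alone, without dye correction. In the first session SD4 lay on the LD and SD4 array alone, so its values and counts for this step depend on that array.

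From SD4 to SD6, the lipid transfer protein DIR1 (MICRO.9831.C2) rose by 4.61 ± 0.13 (adjusted p = 1.1e-05), patatin (MICRO.1520.C3) by 4.60 ± 0.65 and gibberellin 2-oxidase 1 by 4.58 ± 0.29. A chlorophyll a/b-binding protein (MICRO.4177.C7), well above background in 2 of 4 SD6 channels, fell by 5.23 ± 0.27, the unconventional myosin stood at -4.43 ± 0.14 and the photosystem I subunit psaK at -4.30 ± 0.17. Photosynthesis fell at 80 of 138 probes and rose at 6 (81 and 7 adjusted over the list alone, median -1.19, camera adjusted p = 1.74e-16, and 0.171 with an estimated correlation). Starch synthesis rose at 41 of 77 and fell at 2 (43 and 3 adjusted over the list alone, median 0.81, camera adjusted p = 6.15e-11, and 0.236 with an estimated correlation). Cell cycle genes rose at 60 of 110 and fell at 5 (70 and 7 adjusted over the list alone, median 0.59, camera adjusted p = 7.41e-12, and 0.236 with an estimated correlation). Ribosomal proteins rose at 161 of 346 and fell at 2 (174 and 2 adjusted over the list alone, median 0.36, camera adjusted p = 3.9e-13, and 0.228 with an estimated correlation). Their median was 0.215 with median centring. By limma's test 11740 probes differed, 5690 higher and 6050 lower, and 2778 of them by at least 2-fold. The slide as a block gave 13494, median centring 5894, no dye term 1605, the first scan session 454, and the fit without the SD4 and SD6 array 4363. In the first session the photosynthesis median was -0.59 and in the second -1.38, which rests on the SD4 and SD6 array alone, without dye correction. The first session holds SD4 on the LD and SD4 array alone.

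From SD6 to SD8, protease inhibitors rose at 97 of 170 probes and fell at 6 (112 and 7 adjusted over the list alone), with a median of 1.15 (camera adjusted p = 1.14e-34), and this list kept its call with an estimated correlation (adjusted p = 0.0118). Probable serine protease inhibitor 6 (4.62 ± 0.35) and a Kunitz-type inhibitor (MICRO.1751.C22, 4.17 ± 0.25) were among the largest rises, beside a cytochrome P450 (MICRO.9795.C1, 5.23 ± 0.24, adjusted p = 8.6e-05), and a GDSL lipase, well above background in 2 of 4 SD6 channels, rose by 4.39 ± 0.27. Specific tissue protein 2 (-3.57 ± 0.17), a pectate lyase (-3.55 ± 0.41), the Nod26-like channel (-3.17 ± 0.14) and an ethylene-forming ACC oxidase (MICRO.5523.C6, -3.08 ± 0.21) fell furthest. Storage proteins rose at 29 of 64 probes and fell at 5 (38 and 7 adjusted over the list alone, median 1.03, camera adjusted p = 5.48e-09, and 0.134 with an estimated correlation). Cell wall genes fell at 66 of 237 and rose at 16 (80 and 24 adjusted over the list alone, median -0.17, camera adjusted p = 9.66e-08, and 0.0996 with an estimated correlation). By limma's test 3481 probes differed, 1802 higher and 1679 lower, and 1061 of them by at least 2-fold. The slide as a block gave 2397, the first scan session 1935, median centring 1112, no dye term 426 and the fit without the 4 SD4 arrays 64. The protease inhibitor median was 1.13 in the first session and 1.11 in the second, and that of the storage proteins 0.89 and 0.48. Without 1 array the counts were 968 (SD6 and SD8), 1657 (SD4 and SD6), 1843 (SD4 and SD8), 2231 (LD and SD4) and 5535 (SD8 and LD).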

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

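Among the tests below, the spike-in mix test was chosen after its result had been seen, and the list tests of adjacent stages were not in the fixed design. Spreads of quality values were tested for outliers in 20 groups of arrays, and chance marks about 1 in 20 such groups.

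The photosynthesis list was higher in SD4 than in SD2, by a median of 0.98, and fell again from SD4 to SD6, by a median of -1.19. Camera called both at the preset correlation, and neither call held with an estimated one when adjusted over the 23 lists (adjusted p = 0.0577 and 0.171). The tables argue against the normalization of bright probes as the cause, since median centring gave 1.11. A larger share of leaf or other green tissue in the SD4 RNA may explain it but could not be decided. A list of 46 leaf enzymes written before the test rose by a median of 0.236, below about 0.5 of the 0.98 that such tissue was set to need, although camera called it (adjusted p = 7.15e-05, and 0.01 with an estimated correlation). These p-values are adjusted over the marker and photosynthesis lists only, where camera gave photosynthesis an adjusted p of 3.57e-41, and 0.01 with an estimated correlation. The brightest leaf enzymes, glycolate oxidase (MICRO.770.C2, 0.31, adjusted p = 0.114) and transketolase (MICRO.366.C2, 0.40, adjusted p = 0.0791), were not called. The brightest photosynthesis probes moved about as little, and only CP-47 was called. They were MICRO.13166.C1 (0.37, adjusted p = 0.0717), CP-47 (MICRO.6105.C2, 0.46, adjusted p = 0.0452) and MICRO.5012.C1 (0.21, adjusted p = 0.266). The brightest members thus do not tell the lists apart. A slide or scan session stays open as part of the cause, since the first session alone gave 0.463 and the second 1.03. The first value takes SD4 from the LD and SD4 array alone. That of the second session rests on the SD2 and SD4 array alone, without dye correction. Blocks that remove a shift common to a slide or a session gave 0.997 and 0.985. A response of the stolon to the short days themselves was not tested.

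Products of large proteins were noticed among the largest rises in SD2 vs LD, after which their test was set up on the same data. A share of 0.962 of the median of the 6 largest named rises was left after removal of a trend on probe GC content. This cannot decide on GC content, since those rises were picked for their size (3.73 before and 3.59 after removal). Median GC content was 43.3% at rises of at least 2-fold, 40% at all probes and 38.3% at falls of at least 2-fold. Lower integrity or shorter amplified RNA of the LD sample may have contributed: long-transcript products lay 0.243 above short-transcript ones, between the 2 bounds set beforehand, and the difference was 0.272, 0.279 and 0.325 in SD4, SD6 and SD8 vs LD. It was -0.0522, -0.0077 and 0.074 between adjacent short-day stages, so that it lies between LD and the others, where day length and sample cannot be told apart. The LD channels also had the lowest median brightness in both colours, and any part of this in the changes was not tested.

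Spike-in controls, which the comparisons do not use, had a slope of -0.57 on the ratios expected of them on the SD8 and SD2 array. An exchange of the dyes on that array is argued against, since its log ratios correlated at 0.762 across probes (probes are not independent replicates) with those predicted from the other 9 arrays. The best way of giving 2 spike-in mixes to the 5 conditions (LD, SD4 and SD8 with one, SD2 and SD6 with the other) explained 66.4% of the spread, against 37.6% for the second best, and no other of the 100 assignments exceeded 55.6%. One of 2 mixes per condition may lie behind these profiles, but the share lies between the bounds set for it. It does not by itself account for the negative slope, since the SD4 and SD6 array and the LD and SD2 array, with the same mixes in the same dyes under that assignment, had slopes of 0.69 and 0.75. Scored along the difference between the mixes, with -1 expected, the SD8 and SD2 array stood at -0.837, beside -1.01 and -1.08 on those arrays. Its measured spike-in profile was thus not reversed against theirs. No biological explanation was tested.

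The SD2 and SD4 array had 689 spots marked as outliers, far from the other arrays. With the dye effect removed it also had the lowest correlation with its prediction from the other arrays, 0.437. With the dye effect left in, it stood at 0.846, and the SD8 and LD array was lowest at 0.814. The SD8 and LD array had the widest spread of log ratios, with a standard deviation of 1.40, and the largest residual standard deviation, 0.41.

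A total of 1281 probes were called in opposite directions in SD2 vs LD and SD8 vs LD, 562 of them higher in SD2 and lower in SD8 and 719 the reverse, while 5126 were higher in both and 4390 lower in both. Protease inhibitors rose by a median of 1.15 from SD6 to SD8, after medians below LD in SD2, SD4 and SD6. Pathogenesis-related and defence probes rose by a median of 0.58 from SD4 to SD6, after a fall against LD in SD4, and both calls were lost with an estimated correlation (adjusted p = 0.171 and 0.62).

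Other assignments of the 10 pairs to the 10 arrays (100 in all, the real one included) tested chance. As many probes came from only 1 of them, the real one, for the F test (24063 against at most 8068), SD2 vs LD (13989 against 4895), SD4 vs LD (15417 against 3624), SD6 vs LD (19202 against 6709), SD8 vs LD (21218 against 9738), SD6 vs SD4 (11740 against 7821) and the trend (19563 against 7841). For these counts the test argues against a chance match of condition labels and arrays. It reassigns arrays and not extracts, so it cannot tell a response to day length from differences between single samples. For SD4 vs SD2, 3 assignments gave as many as the 1114 called, the real one included, and the highest other gave 4162. For SD8 vs SD6, 2 gave as many as the 3481 called, and the highest other gave 14006. These shares are low, but assignments with several times the real count point to a structure of the samples, whose nature was not tested. The SD4 vs SD2 count is not firm for the reasons given with it.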

How the results depend on the processing

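The fits without the 4 SD4 or 4 LD arrays, the first scan session, the session block, the 2-fold minimum and the deposited table read as log2 throughout were chosen after seeing the data. Counts within 1.5 times those of the report are left out, and the cause was not tested unless it is given.

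Without a dye term the counts were 7435 (F test), 1956 (SD2 vs LD), 2610 (SD4 vs LD), 6731 (SD6 vs LD), 9006 (SD8 vs LD), 4 (SD4 vs SD2), 1605 (SD6 vs SD4), 426 (SD8 vs SD6) and 6451 (trend), where the dye effect (median size 0.32) falls into the residual. A 2-fold minimum, stricter by construction, gave 3690, 4178, 7471 and 9139 for SD2, SD4, SD6 and SD8 vs LD, and 262, 2778 and 1061 for the steps. The first scan session, with fewer arrays, gave 8592 (SD2 vs LD), 3556 (SD4 vs LD), 4 (SD4 vs SD2), 454 (SD6 vs SD4) and 1935 (SD8 vs SD6). In that session SD4 lay on the LD and SD4 array alone. Without the 4 SD4 arrays the counts were 1099 (SD2 vs LD), 7312 (SD6 vs LD), 10515 (SD8 vs LD) and 64 (SD8 vs SD6). Median centring gave 198, 5894 and 1112 for the 3 steps. Its totals in SD2 and SD4 vs LD (17598 and 16377) lay within 1.5 times, but shared only 7560 of the 13989 and 8274 of the 15417 calls. The deposited table read as log2 gave 7565 (SD2 vs LD), 332 (SD4 vs SD2) and 2114 (SD8 vs SD6), and array weights gave 24599 (SD4 vs LD). Separate channels gave 6321 for SD8 vs SD6.

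For SD4 vs SD2 further counts were 1765 (scanner's log ratio), 1916 (above background in all 20 channels), 2186 (slide as a random block), 1933 (trended prior), 6854 (array weights), 3977 (separate channels), 2289 (deposited table) and 0 with the slide as a block, where limma had 7432 at an unadjusted p under 0.05. The share that rose was 32.8%, but 47.5% with median centring, 48.5% with separate channels and 52.6% with array weights, which turned the majority.

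Leaving out 1 array gave 19826 to 28097 (F test), 5554 to 17304 (SD2 vs LD, lowest without the LD and SD2 array), 7332 to 18029 (SD4 vs LD, lowest without the LD and SD4 array), 15350 to 20365 (SD6 vs LD), 18672 to 22392 (SD8 vs LD), 17 to 3068 (SD4 vs SD2, lowest without the SD2 and SD4 array and highest without the SD8 and LD array), 4363 to 16078 (SD6 vs SD4, lowest without the SD4 and SD6 array), 968 to 5535 (SD8 vs SD6, lowest without the SD6 and SD8 array and highest without the SD8 and LD array) and 14982 to 23880 (trend).

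Of 263 values of named probes, direction and call held in 260 without background subtraction, 247 with median centring, 249 with the slide as a block, 226 in the first scan session and 217 without a dye term. GIGANTEA (MICRO.9300.C1) reversed to 0.05 (0.0504) with median centring, and CONSTANS-LIKE 16 (MICRO.17979.C1) to 0.03 (0.0343) in the first scan session. Median centring moved the median of all probes from -0.08 to 0.04 in SD2 vs LD and from 0.01 to -0.13 in SD6 vs LD.

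In SD8 vs LD the gibberellin list lost its call with all 20 channels required (median -0.98, adjusted p = 0.245) and with the deposited table (-1.29, 0.0652), where the fall was larger than -0.61, and in the first session (-0.35, 0.0694) and without the SD8 and LD array (-0.41, 0.111), where it was smaller. Defence lost it with all 20 channels required (0.102), and heat shock with median centring (0.0522), without a dye term (0.0576), with the deposited table read as log2 (0.0649) and in the first session (0.0694). Sucrose metabolism gained a call in 13 settings (adjusted p from 0.0128 to 0.0495). Phenylpropanoids gained one with the slide as a block (0.0367) and without the SD6 and LD array (0.043). Separate channels gave no list values. Signal over background limits the LD and SD4 array most, where 59.9% of probes stood above it in red.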

Other observations

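The lists of adjacent stages below were tested outside the fixed design.

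Several lists gave no call by camera in SD8 vs LD, although many of their members changed. By fry, which tests whether members move on balance one way and compares them with no other probes, 4 of these lists did not pass: circadian clock (adjusted p = 0.0553), jasmonate (0.0598), cytokinin (0.103) and glycoalkaloids and sterols (0.839). The others passed, with adjusted p from 7.29e-05 for abscisic acid to 0.034 for the flowering and tuberization regulators. Sucrose metabolism and transport had 48 higher and 24 lower of 109 probes (49 and 25 adjusted over the list alone; median 0.37, camera adjusted p = 0.0523), with fructokinase 2 at 3.50. Cytokinin had 17 higher and 10 lower of 37 (19 and 11 adjusted over the list alone; median 0.53, adjusted p = 0.382). Cell wall genes had 76 higher and 93 lower of 237 (77 and 94 adjusted over the list alone; median -0.01, adjusted p = 0.231), among them 2 expansin-related probes at -2.85 and -2.99. Auxin had 58 higher and 68 lower of 195 (62 and 70 adjusted over the list alone; median -0.08, adjusted p = 0.5), with an auxin-repressed protein (MICRO.13674.C1) at -4.08. Abscisic acid and dehydration had 28 higher and 37 lower of 93 (28 and 38 adjusted over the list alone; median -0.14, adjusted p = 0.115). Ethylene had 38 higher and 55 lower of 141 (41 and 56 adjusted over the list alone; median -0.11, adjusted p = 0.211). Jasmonate and lipoxygenase had 17 higher and 16 lower of 56 (17 and 16 adjusted over the list alone; adjusted p = 0.995), and its median of -0.02 and its mean of 0.15 differ in sign. Its 12-oxophytodienoate reductase (MICRO.9373.C1), an enzyme of jasmonate synthesis, rose by 3.90.

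The circadian clock list had 7 higher and 9 lower of 26 probes (7 and 9 adjusted over the list alone; median -0.16, camera adjusted p = 0.586). Suberin and periderm had 5 higher and 7 lower of 25 (5 and 7 adjusted over the list alone; median -0.16, adjusted p = 0.42). Phenylpropanoids had 44 higher and 76 lower of 194 (45 and 77 adjusted over the list alone; median -0.15, adjusted p = 0.0712). Glycoalkaloids and sterols had 28 higher and 25 lower of 79 (29 and 27 adjusted over the list alone; adjusted p = 0.979), and the median of -0.03 and the mean of 0.14 differ in sign. Root uptake markers had 21 higher and 20 lower of 55 (22 and 20 adjusted over the list alone; median 0.09, adjusted p = 0.715).

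Between adjacent stages camera also called lists that lost their call with an estimated correlation. From SD2 to SD4 ribosomal proteins had a median of 0.07 (adjusted p = 0.0048, then 0.65). From SD4 to SD6 storage proteins rose by 0.47 (4.24e-07, then 0.189), protease inhibitors by 0.54 (7.35e-10, then 0.114) and defence probes by 0.58 (2.55e-09, then 0.171). The storage protein median was 0.46 in the first scan session, 0.97 in the second (the SD4 and SD6 array alone) and 0.78 with median centring. Lower medians came from abscisic acid (-0.22; 0.00241, then 0.114), cell wall (-0.17; 0.0267, then 0.274), auxin (-0.10; 0.0283, then 0.418) and circadian clock (-0.13; 0.0283, then 0.236). From SD6 to SD8 starch synthesis rose by 0.51 (2.79e-07, then 0.415) and starch breakdown by 0.16 (0.00929, then 0.458), while gibberellin (-0.22; 0.00414, then 0.216), ethylene (-0.07; 0.0109, then 0.216) and phenylpropanoids (-0.09; 0.0161, then 0.134) had lower medians.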
